A study of Mus musculus with 4 samples.

How the data were processed

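RNA of the tibialis anterior muscle (TA, a fast-twitch muscle of the lower leg) and of the heart was measured on Affymetrix mouse arrays, which read each transcript with sets of short probes. The mice were MG56 knockouts and wild types on the C57BL/6J background at postnatal day 9, per the labels. MG56 is an alternative name of Hhatl. Per the series' design text, RNA of 3 knockout mice was mixed before hybridisation, and so was RNA of wild-type mice, whose number is not given in the sources used here. Each of the 4 groups (knockout TA, wild-type TA, knockout heart, wild-type heart) therefore has 1 array of pooled RNA. No replicate error can be computed, no p-value is given, and a ratio compares pools of RNA and not populations of mice.

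The values deposited by the authors are signal intensities on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes. Its version, its scaling target and the detection calls are not given in the sources used here. The trimmed means of the 4 arrays (2% left off at each end) lay between 496.35 and 496.83, so the arrays share 1 scale as deposited. The signals of 45037 probe sets ran from 0.1 to 52162, and control probe sets were not analysed here. The number of arrays limits the precision.

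Probe sets were named from the annotation table of the platform. In it 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were used for genes. Of these, 34741 matched a RefSeq gene by gene identifier (assembly GRCm38.p6, used for names and gene order only), and 0 symbols needed an update. No coordinates are given because the array's build is not given in the sources used here.

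The median of all signals, 101.3, served as a floor. A gene was measured in a comparison if at least 1 of the arrays compared reached the floor, and lower signals were raised to it. Where the floor replaced a signal, the fold is a lower bound and is written "at least". Where a gene had several probe sets, the one with the highest mean signal over the 4 arrays stood for it. Ratios are log2 of knockout over wild-type signal, on the arrays as deposited, since the median log2 ratio was -0.01 in TA and -0.002 in heart and so below the limit of 0.1 for recentring. Genes with a ratio of at least 2-fold were counted. Members of gene lists were counted at 1.5-fold, and the median of a list was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. Such a percentile describes these arrays only, and lists with under 5 measured members got none.

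Before the data were examined, 38 gene lists, the floor, the thresholds, the naming rule and the alternatives were fixed; 8 more lists were written later, most of them after some of their members' values had been seen. The rule named the targeted gene, the 10 genes with the largest ratios each way in each knockout comparison, the 5 largest each way between the wild-type tissues and for the difference between tissues, and up to 4 members of a list with the largest ratios. Clone names, unnamed transcripts, immunoglobulin segments and genes whose other probe sets pointed the opposite way were passed over in the rankings and still counted. Genes behind small counts were added. Hspa5, Hsp90b1, Ddit3 and Xbp1 were chosen after their values were seen.

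The computation was tested on simulated arrays, 20 for each tissue, with the spread of log2 ratios in each range of signal taken from the real arrays. With noise added to the wild-type array, changes were planted only in genes with a wild-type signal of at least 4 times the floor. Among these, genes changed 2-fold were called in 45.9% of cases in TA and 47.6% in heart. Genes changed 3-fold were called in 99.4% and 99.5%. For dimmer genes no such rate was computed. This first noise model called a median of 151 unchanged genes at 2-fold in TA and 178 in heart. It also gave a median of 59.5 and 66 unchanged genes at 3-fold, more than the real arrays hold in all. A second noise model was therefore written after the first had been compared with the real counts. It centres each gene on the mean of the arrays of a tissue and splits the same spread over them. It called a median of 27.5 and 44 unchanged genes at 2-fold, and 4 and 4 at 3-fold. Both models are given because the choice between them was made with the real counts known. In the first model, 4% of 100 unchanged lists in TA and 5% in heart fell outside the central 95% of random lists. These lists were drawn at random from genes with independent noise, so such a share was set by construction. It says nothing about lists of genes that vary together.

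The comparisons were knockout against wild type in TA and in heart, TA against heart in wild type, and the difference between the tissues' log2 ratios. Alternatives were centred ratios, quantile normalization over all 4 arrays or within a tissue, a floor at the 25th or 75th percentile or none, other rules for several probe sets, thresholds of 1.5-fold and 3-fold, and random lists without matching. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.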

Results

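Transcript levels in TA muscle and heart of mice lacking MG56 (Hhatl), a membrane protein of the endoplasmic and sarcoplasmic reticulum of striated muscle, were compared with those of wild-type mice at postnatal day 9. There were 4 arrays, 1 for each genotype and tissue, and between 49.5% and 50.7% of the probe sets of an array lay above the floor. With signals under the floor raised to it, the log2 signals of knockout and wild type correlated across probe sets at 0.990 in TA and 0.991 in heart. Those of wild-type TA and heart correlated at 0.933. These are correlations across probe sets, which are not independent replicates.

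Hhatl itself was lower in both knockout pools. Its signal in TA was 1078 in the knockout and 5491 in the wild type, 5.09-fold lower, and in heart it was 880 and 2110, 2.40-fold lower. The array has 1 probe set for the gene. Whether it lies in the deleted part is not given in the sources used here, so the remaining signal says nothing about the allele.

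In knockout TA, genes for protein folding in the endoplasmic reticulum (ER) were far higher than in wild-type TA. Sdf2l1, a component of ER chaperone complexes, was 20.03-fold higher, with a signal of 5369 against 268. Creld2 was 11.6-fold higher, Herpud1, which takes part in ER-associated degradation, 9.30-fold, the disulfide isomerase gene Pdia4 7.82-fold, the secreted ER stress protein gene Manf 7.18-fold and the ER co-chaperone gene Dnajb9 6.28-fold. Of the 31 measured genes of the list of ER chaperones and ER-associated degradation, 26 were at least 1.5-fold higher in the knockout pool, 20 of them at least 2-fold, and 0 were 1.5-fold lower. The median log2 ratio was 1.46, at percentile 100 of the random lists. The major ER chaperone genes Hspa5 and Hsp90b1 were 3.85-fold and 3.56-fold higher, and Xbp1, a transcription factor gene of the unfolded protein response, 2.02-fold. In the later list of N-glycosylation and translocon genes, 12 of 29 were at least 1.5-fold higher and 0 lower (median 0.50, percentile 100). Spcs2 was 2.45-fold, Alg12 2.34-fold and Uggt1 2.28-fold higher. Ssr1 belongs to this list and to the ER chaperone list, so the lists are not independent. The later list of ER-to-Golgi coat genes had 5 of 25 higher and 0 lower (median 0.40, percentile 100), among them Sec23b at 2.01-fold and Sec24b at 1.89-fold.

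Targets of ATF4 and the integrated stress response were higher as a group in knockout TA. Trib3, a pseudokinase gene of that response, was 8.16-fold higher, Asns, which encodes asparagine synthetase, 8.04-fold, the hormone gene Fgf21 at least 6.78-fold and the mitochondrial folate enzyme gene Mthfd2 4.22-fold. Of 42 measured members, 23 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.64 at percentile 100. Ddit3, which encodes the transcription factor CHOP, was 3.93-fold higher. In the later list of serine and one-carbon synthesis, 4 of 12 genes were 1.5-fold higher and 0 lower (median 0.24, percentile 99.3), and the log2 ratio of Psat1 was 2.001. Its higher genes Mthfd2, Psat1 and Phgdh also belong to the integrated stress response list, so the lists are not independent. The later list of the mitochondrial unfolded protein response had a median of 0.17 (percentile 99.0, or 97.2 among unmatched lists) and 0 of its 12 genes reached 1.5-fold, Hspa9 having a log2 ratio of 0.57. Among the heat shock genes, 3 of 22 were 1.5-fold higher and 0 lower (median 0.09, percentile 98.7), with Hspa1a 2.20-fold, Hspa1b 1.92-fold and Bag3 1.53-fold higher. Among unmatched random lists its percentile was 92.1. The heat shock list also holds Hspa9, so it overlaps the mitochondrial list. Fam174b, outside these lists, was 5.42-fold higher.

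Genes of muscle atrophy and FoxO activity included several that were higher in knockout TA. Eda2r, a receptor gene of the tumour necrosis factor receptor family, was 4.44-fold higher, the muscle ubiquitin ligase gene Fbxo32 3.77-fold, Klf15 2.52-fold and the metallothionein gene Mt1 1.76-fold. This list had 5 of 22 genes 1.5-fold higher and 0 lower (median 0.21, percentile 99.97), and its median was 0.07 when a gene was taken as the median over its probe sets. Immediate early genes had 5 of 19 higher and 0 lower (median 0.34, percentile 100), with Atf3 2.94-fold and Fos 2.57-fold. In the list of fatty acid oxidation and fasting, 4 of 27 were higher and 1 lower (median 0.12, percentile 99.9), with the acyl-CoA thioesterase gene Acot2 4.18-fold and Acot1 1.95-fold higher and Ucp3 1.65-fold lower. Glucocorticoid-responsive genes had 4 of 19 higher and 1 lower (median 0.16, percentile 99.4), including Cdkn1a at 2.32-fold and Per1 at 1.84-fold higher. Klf15 and Mt1, also higher, belong to this list and to the atrophy list, so the lists are not independent. The list of denervation and immature junction had 4 of 18 higher and 0 lower around a median of -0.01 (percentile 52.2), with Ankrd1 2.45-fold and Sln 1.77-fold higher. With the floor at the 75th percentile, which leaves out its dimmer members, the median of this list was 0.57. Autophagy and lysosome genes had a median of 0.04 (percentile 88.0), and 2 of 31 were 1.5-fold higher, Sqstm1 at 2.05-fold and Atg13 at 1.90-fold, against 1 lower, Tfeb at 1.59-fold.

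The contractile and calcium-handling genes of TA differed less. Adult fast fibre sarcomere genes lay slightly lower as a group (median -0.23, percentile 0.15), although of 16 only Myh2, the myosin 2A heavy chain gene, passed 1.5-fold, at 1.51-fold lower. Over all alternatives that median ran from -0.39 to -0.14. With quantile normalization within the tissue, it was -0.14 and the log2 ratio of Myh2 -0.53. In the list of the sarcoplasmic reticulum and calcium release (median -0.13, percentile 3.55), 2 of 33 genes were 1.5-fold higher and 3 lower. The calcium pump gene Atp2a2 was 2.17-fold higher, while Stac3 was 1.87-fold and Trdn 1.53-fold lower. Trdn had a log2 ratio of -0.61, and of -0.19 on the probe set that is brightest in TA. The embryonic and neonatal sarcomere list had 2 of 13 higher and 1 lower (median 0.10, percentile 97.6, or 89.1 among unmatched lists), with Csrp3 2.18-fold and Myl4 1.87-fold higher and Mybph 1.89-fold lower. Slow fibre sarcomere genes had a median of -0.03 (percentile 69.5), myogenic regulators and satellite cell genes -0.08 (percentile 16.1), glycolysis genes -0.12 (percentile 4.86) and oxidative phosphorylation genes -0.11 (percentile 16.8). The hedgehog pathway list had a median of -0.01 (percentile 46.2), and 0 of its 12 genes reached 1.5-fold.

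Cell division genes were lower in knockout TA. The mitotic kinase genes Aurkb, Bub1 and Melk were 3.01-fold, 2.95-fold and 2.95-fold lower, the kinetochore genes Zwilch and Nuf2 2.94-fold and 2.72-fold, and the proliferation marker Mki67 2.58-fold. Of 32 measured cell cycle genes, 25 were at least 1.5-fold lower and 1, Mcm2, higher, with a median log2 ratio of -1.05 at percentile 0. Other genes with the largest deficits were Exoc3l4 at 3.95-fold, the muscle gene Ky at 3.28-fold, the lipogenic regulator Thrsp at 2.97-fold and Kif26a at 2.91-fold. The genotypes' pools also differed in sex-linked transcripts. The Y-linked genes Uty, Eif2s3y and Kdm5d were 2.71-fold, 1.78-fold and 1.57-fold higher and Xist 1.44-fold lower in knockout TA. Markers of other cell types moved little as groups in TA. Fibroblasts and matrix had a median of -0.12, endothelium -0.01, leukocytes 0.12, adipocytes -0.08, Schwann cells and nerve -0.01, cartilage, bone and tendon -0.14, and red blood cells -0.28 at percentile 1.05. The direction of the last depends on the floor, as its median was 0.06 with the floor at the 25th percentile and 0.13 with none. Single markers differed more, with the neutrophil gene S100a8 5.26-fold higher.

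In all, 11556 genes were measured in TA, of which 110 were at least 2-fold higher and 106 at least 2-fold lower in the knockout pool, and 31 and 4 at least 3-fold. Simulated TA arrays gave a median of 151 unchanged genes at 2-fold under the first noise model and 27.5 under the second, against the 216 observed. How many of the 216 are noise therefore depends on the noise model. With the floor at the 75th percentile, the counts were 61 and 24, against simulated medians, over both directions, of 10 under the first model and 0 under the second. Where a second probe set was measured, 50 of 52 of the higher and 39 of 40 of the lower genes differed in the same direction on it. Only 41 of 52 and 23 of 40 did so by at least 1.5-fold.

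**Figure D1:**
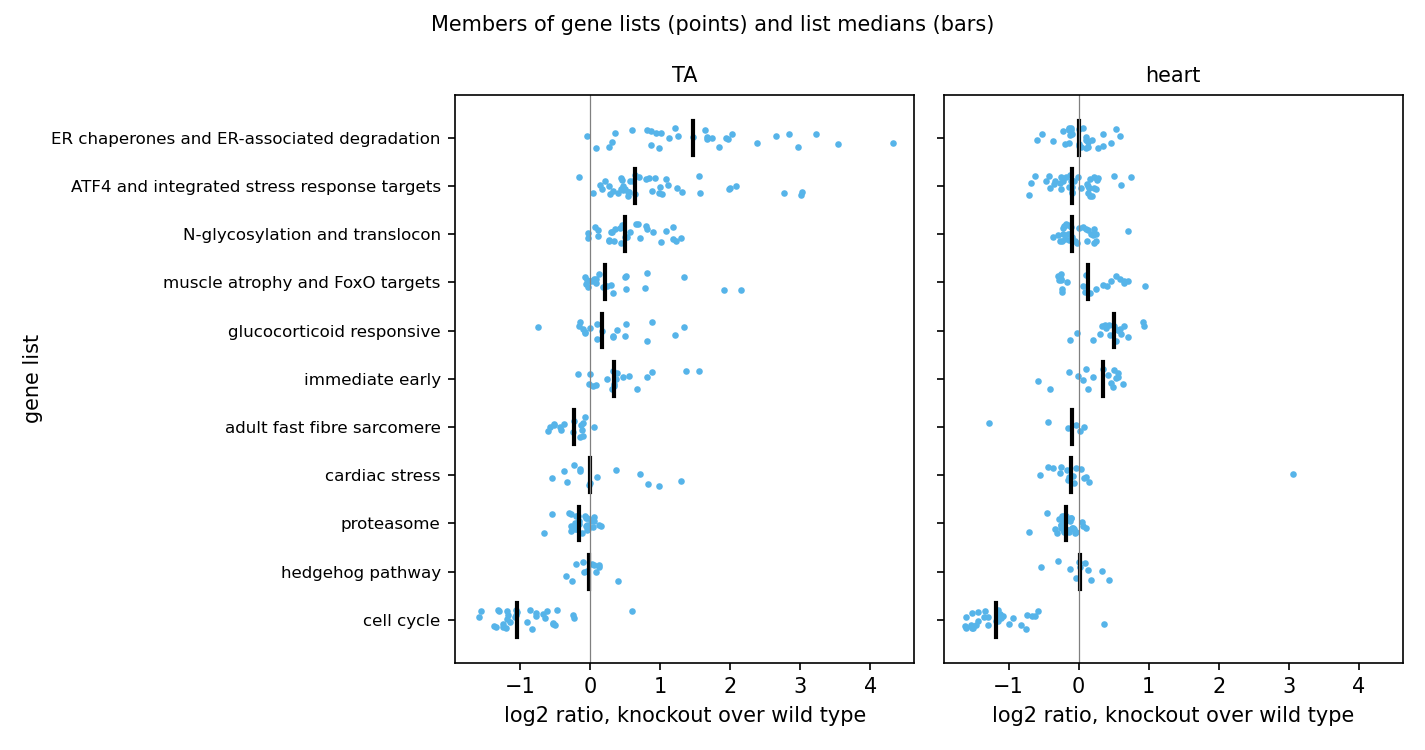
Log2 ratios of knockout over wild-type signal (x axis) in TA (left) and heart (right) for the measured members of 11 gene lists (y axis), 1 point per gene, with a black bar at the list's median. The median of the ER chaperone list is 1.46 in TA and 0.01 in heart, and that of the cell cycle list is -1.05 and -1.18.

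In knockout heart, the largest difference upwards was in Myh7, the gene of the slow, beta isoform of the cardiac myosin heavy chain. Its signal was 7354 in the knockout and 886 in the wild type, 8.30-fold higher. Timp4, an inhibitor gene of matrix metalloproteinases, was 3.74-fold higher, and a second probe set pointed the same way. Slc10a6 was at least 2.94-fold higher, Ms4a4d 2.91-fold, Farsa 2.73-fold, the alcohol dehydrogenase gene Adh1 2.65-fold, Gfra1 at least 2.61-fold, Krtap12-1 at least 2.58-fold and Wnt7a 2.52-fold. Rps27 was 2.62-fold higher on a probe set with a wild-type signal of 104, close to the floor. Farsa and Wnt7a were dim as well, with wild-type signals of 164 and 122. Of the higher genes named here, only Timp4 had more than 1 measured probe set.

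Other genes linked to cardiac stress did not accompany Myh7. In that list only Myh7 among 16 measured genes passed 1.5-fold (median -0.11, percentile 6.55), and the natriuretic peptide gene Nppa and the skeletal actin gene Acta1 were 1.29-fold and 1.47-fold lower. Tnni1, the slow skeletal troponin I gene of the fetal heart, was 1.76-fold higher, and it was the only 1 of 9 genes of the embryonic and neonatal sarcomere list past 1.5-fold (median 0.05, percentile 93.8). The slow fibre list had 2 of 12 genes higher, Myh7 and Tnni1 (median 0.04, percentile 87.6). The adult cardiac maturation list had a median of 0.04 (percentile 97.0, or 71.4 among unmatched lists) and 0 of 18 genes past 1.5-fold. Among genes of the atrium and conduction tissue (median -0.11, percentile 9.08), Tbx5 was 2.06-fold higher. Of the 20 skeletal muscle label genes, 13 were under the floor in both heart pools. The other 7 had a median of -0.42 (percentile 0.02), with 3 above 0 and 4 below, and 2 passed 1.5-fold, Casq1 at 2.73-fold and Myl1 at 2.42-fold lower. This median was 0.07 without the probe sets that can match several transcripts.

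Cell division genes made up most of the named deficits in knockout heart. Kif2c was 3.66-fold lower (log2 ratio -1.87, or -0.65 as the median over its probe sets), Ect2 3.65-fold, Melk 3.61-fold, Depdc1a 3.52-fold, Racgap1 3.28-fold, Spag5 at least 3.15-fold, Nuf2 and Spc24 both 3.13-fold and Cdca5 3.10-fold. Of 32 measured cell cycle genes, 30 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.18 at percentile 0. Ucp1, the uncoupling protein gene of brown fat, was at least 3.24-fold lower, and among 10 adipocyte genes (median 0.06, percentile 76.5) Car3 was 2.17-fold lower and Pparg at least 2.26-fold higher. The Y-linked genes Uty, Eif2s3y and Kdm5d were 2.29-fold, 2.21-fold and 1.64-fold higher and Xist 1.30-fold lower in the knockout pool. Medians of other cell types were -0.10 for fibroblasts and matrix, -0.02 for endothelium, 0.06 for leukocytes and -0.12 for red blood cells.

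Genes responsive to glucocorticoids were placed high in knockout heart, with 6 of 19 at least 1.5-fold higher and 0 lower (median 0.51, percentile 100). Sult1a1 was 1.91-fold higher, the clock gene Per1 1.88-fold and the metallothionein genes Mt2 and Mt1 1.63-fold and 1.56-fold. Immediate early genes had a median of 0.34 (percentile 99.99) with 1 of 17 past 1.5-fold, Btg2. Fatty acid oxidation and fasting genes had a median of 0.12 (percentile 100), with Acot1 2.04-fold and Ppargc1a 1.56-fold higher. The atrophy and FoxO list had 5 of 22 higher and 0 lower (median 0.13, percentile 99.1), including Foxo4 at 1.93-fold. Its higher genes Mt1 and Mt2 also belong to the glucocorticoid list, so the lists are not independent. In the list of cholesterol and lipid synthesis, 6 of 26 genes were at least 1.5-fold lower and 0 higher, while 11 lay above 0 and 15 below (median -0.12, percentile 2.09). The median was -0.03 with the floor at the 75th percentile. Sqle, which encodes squalene epoxidase, was 2.84-fold, Idi1 2.26-fold and the regulator Srebf2 1.93-fold lower, with a log2 ratio of -0.95, or -0.51 as the median over its probe sets. Proteasome genes lay slightly lower (median -0.18, percentile 0.02), with 1 of 31 past 1.5-fold.

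The ER chaperone list, so high in TA, had a median of 0.01 in heart (percentile 66.6). There, 1 of its 31 genes was 1.5-fold higher, Dnajb9 at 1.51-fold, and 1 was lower, Sdf2l1 at 1.52-fold. Hspa5 was 1.07-fold higher and Hsp90b1 1.10-fold lower. Integrated stress response targets had a median of -0.09 (percentile 2.73), or -0.01 with the median over probe sets, with 2 of 38 higher, Cebpb and Ddit4, and 3 lower, Slc7a5, Phgdh and Psat1. The hedgehog pathway list had a median of 0.02 (percentile 58.6), and 0 of its 11 genes reached 1.5-fold.

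In heart, 11478 genes were measured, of which 37 were at least 2-fold higher and 136 at least 2-fold lower, and 3 and 18 at least 3-fold. Simulated heart arrays gave a median of 178 unchanged genes at 2-fold under the first noise model, no fewer than the 173 observed, and 44 under the second. With the floor at the 75th percentile the counts were 8 and 37, against simulated medians, over both directions, of 11 under the first model and 0 under the second. Of the genes with a second probe set, 8 of 9 of the higher and 51 of 53 of the lower differed in the same direction on it. Only 5 of 9 and 32 of 53 did so by at least 1.5-fold.

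Set side by side, both tissues had a deficit in cell division genes, larger in heart, and they differed more in the ER genes. For the cell cycle list the median of the TA log2 ratio minus that of heart was 0.23 (percentile 99.9), with 25 of 32 genes above 0. Among 10843 genes measured in both, 56 were at least 2-fold lower in both knockout pools, where 1.21 would be shared by independent lists, and 17 of them belonged to the cell cycle list. The 56 included Mki67, Top2a, Birc5, Bub1, the targeted gene Hhatl and the sterol gene Sqle. Cell division genes outside that list, such as Melk, Nuf2, Racgap1, Spc24 and Cdca5, were also among the 56, so 17 understates the share of cell division. Only Uty was 2-fold higher in both, against 0.292 for independent lists; with the median over probe sets, 0 genes were. Only Mettl7a2 lay 2-fold apart in opposite directions, 2.54-fold lower in TA and 2.40-fold higher in heart. Across genes, which are not independent replicates, the log2 ratios of the tissues correlated at 0.313 (Pearson) and 0.273 (Spearman). Without the cell cycle list the Pearson correlation was 0.293, with the cell division genes outside that list still included. Whether both tissues came from the same mice is not given in the sources used here. If they did, chance differences between the pooled mice, their sex makeup included, are shared by the tissues, and independent lists are then not the value without an effect of genotype.

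The difference between the tissues' log2 ratios was largest towards TA for Sdf2l1 at 4.92, Creld2 at 3.43, Asns at 3.12, Pdia4 at 3.10 and Manf at 2.84. Towards heart it was -3.07 for Myh7, -2.61 for Mettl7a2, -2.20 for Kif26a, -1.85 for Ms4a4d and -1.79 for Clec2d. For the ER chaperone list the median difference was 1.34 and for the integrated stress response list 0.70, both at percentile 100. In all, 17 genes differed by at least 4-fold towards TA and 3 towards heart, the latter being Myh7, Mettl7a2 and Kif26a. No test of these differences was possible with 1 pool per group.

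**Figure D2:**
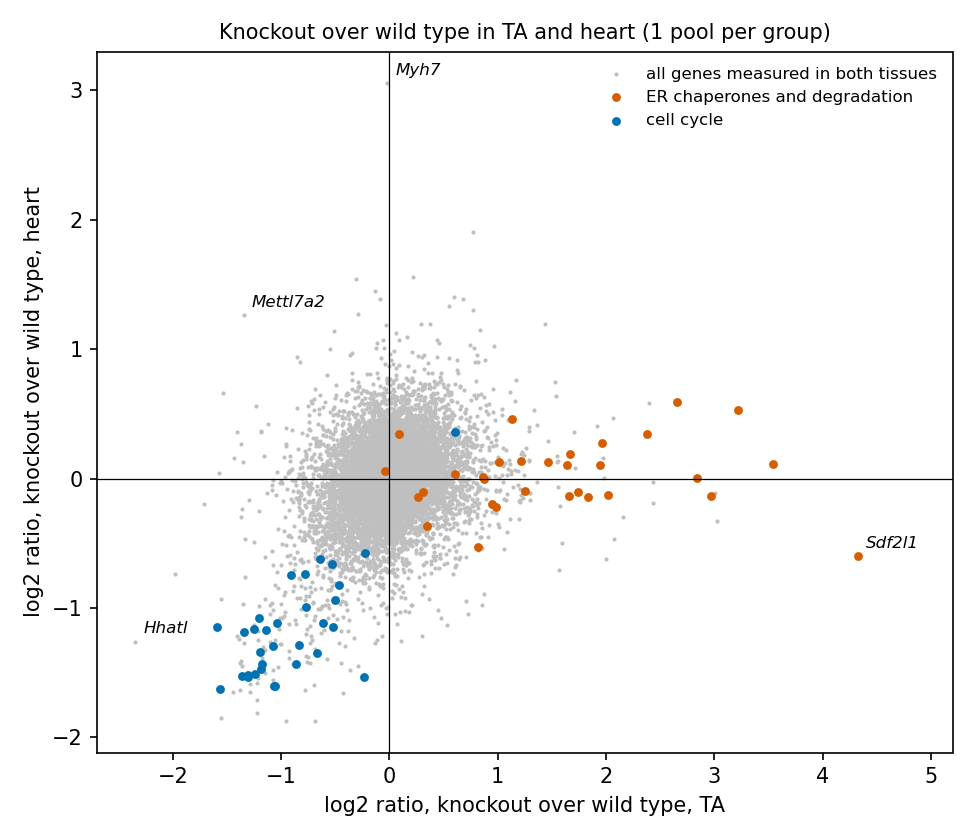
Log2 ratio of knockout over wild-type signal in TA (x axis) against heart (y axis), 1 grey point for each of 10843 genes measured in both tissues, with the ER chaperone list in orange and the cell cycle list in blue. Sdf2l1 stands at 4.32 in TA and -0.60 in heart, while most cell cycle genes are lower in both.

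The wild-type arrays separated the tissues as labelled. Fast skeletal muscle genes led in TA, with Tnnt3 at least 459-fold, Mylpf at least 448-fold, Pvalb at least 384-fold and Myh8 at least 384-fold above heart. Myh1 was at least 468-fold higher on its brightest probe set, which can match several transcripts. Without such probe sets its log2 ratio was 2.37 on a dimmer probe set. In heart, Tnni3 was at least 295-fold, Nppa at least 253-fold, Mybpc3 at least 239-fold, Pln 237-fold and Dsp at least 211-fold above TA. Of 20 skeletal muscle label genes, 18 were at least 2-fold higher in TA, and of 19 cardiac label genes, 17 were at least 2-fold lower. Hhatl was 2.60-fold higher in wild-type TA than in heart. Of 11887 genes measured, 894 were at least 2-fold higher and 922 at least 2-fold lower in TA.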

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

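The tests of non-muscle cells, skeletal muscle, developmental stage and thyroid hormone, and the comparisons with sex-linked genes, were chosen only after the result was seen. Named genes that lay at least 1.5-fold apart in opposite directions in the tissues are given first, and none of these differences was tested, because each group has 1 pool. Sdf2l1 had a log2 ratio of 4.32 in TA and -0.60 in heart, Psat1 2.001 and -0.62, Slc7a5 1.56 and -0.71, Phgdh 0.61 and -0.68, and Srebf2 0.70 and -0.95. Srebf2 was 0.05 in TA and -0.51 in heart as the median over its probe sets, and Psat1 was -0.52 in heart. Phgdh was -0.56 in heart on the probe set that is brightest there. Kif26a had -1.54 in TA and 0.66 in heart, and Mettl7a2 -1.35 and 1.26. Among probe sets without a single gene name, which the comparisons leave out, 19 of 3221 measured were at least 2-fold higher and 26 lower in knockout TA. In knockout heart 33 of 3477 were higher and 16 lower, a balance opposite to that of the named genes, of which 37 were higher and 136 lower.

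The ER chaperone genes were higher in knockout TA. The scaling of the arrays was argued against, since the lowest median of the list over 3 other scalings was 1.47. Secretory cells of another type would bring their own markers, but the highest median of the fibroblast, plasma cell and cartilage and bone lists in TA was -0.12. A change in sex makeup alone would raise a transcript by no more than it raises Y-linked genes. Those measured were 1.57-fold to 2.71-fold higher in TA. The list's median was 2.76-fold there. In heart those genes were 1.64-fold to 2.29-fold higher, while the list's median log2 ratio was 0.01. The TA values cannot decide on sex makeup. Uty at 2.71-fold lies close to the list's median, and its wild-type signal of 157.5 lies near the floor. The heart values argue against a sex effect of the same size in both tissues. The genotype may account for the pattern, as may feeding, growth or a sex effect confined to TA, and these stay open with 1 pool per group.

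The cell cycle genes were lower in both knockout tissues. A loss of non-muscle cells was argued against, since the lowest median of the fibroblast, endothelium and leukocyte lists over both tissues was -0.12. Noise of low signals was argued against too: with the floor at the 75th percentile, the higher of both medians was -0.64, from 21 members in TA and 26 in heart. A lower share of females would lower a transcript by no more than Xist. On any of its probe sets, the log2 ratio of Xist was no lower than -0.81 in TA and -0.65 in heart. The cell cycle medians were -1.05 and -1.18, which argues against the sex makeup of the pools as the only source. Slower growth of the knockout mice is a candidate explanation that was not tested, beside the genotype.

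For the higher Myh7 in knockout heart, skeletal muscle in the heart pool is argued against by its abundant transcripts: Tnnt3 had a signal of 46476 in wild-type TA and 35.1 in knockout heart, where Myh7 stood at 7354 against 12191 in wild-type TA. The 7 skeletal label genes measured in heart went both ways, with a median of -0.42 that was 0.07 without probe sets that can match several transcripts. A younger heart would hold more dividing cells, while the cell cycle median was -1.18. That deficit was already known and was shared by TA, at -1.05, so it cannot decide on the stage of the heart. Tnni1, a troponin gene of the fetal heart, was 1.76-fold higher. It was the only 1 of 9 embryonic and neonatal sarcomere genes past 1.5-fold. Lower thyroid hormone action should lower a set of genes that in heart had a median of 0.0408 (percentile 79.3), with 0 of 13 past 1.5-fold. They were not lower as a group, but went both ways, with 7 above 0 and 6 below, so this explanation stays open. An effect of the genotype may be another explanation, and the difference rests on 1 probe set.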

How the results depend on the processing

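No paired analysis was possible because the groups share 1 replicate number, a number that only names arrays here. No array could be left out, as each group has 1. A model with additive genotype and tissue terms was not run; with 1 residual degree of freedom, it would take the difference between the tissues as its error. Other scalings and the choice of probe set in the tissue kept every count of genes within 1.5 times. Counts of higher and lower genes followed the floor and the threshold, by construction. With the floor at the 25th percentile they were 368 and 415 in TA, 277 and 480 in heart, and 1441 and 1434 for wild-type TA over heart. At the 75th percentile they were 61 and 24, 8 and 37, and 491 and 470, and with no floor 1374 and 1456, 1316 and 1574, and 2412 and 2516. At 1.5-fold they were 487 and 512, 308 and 480, and 1713 and 2141, and at 3-fold 31 and 4, 3 and 18, and 443 and 356. Genes higher in both tissues numbered 19, 0 and 289 under these floors, 0 with the median over probe sets, 35 at 1.5-fold and 0 at 3-fold. Genes lower in both numbered 106, 13 and 406 under these floors, 158 at 1.5-fold and 0 at 3-fold. The correlation of the tissues' log2 ratios was 0.168, 0.338 and 0.0642 under the same floors. Signals near background limit the results in this way.

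With the floor at the 75th percentile, 11 of the 21 cell cycle genes still measured in TA and 19 of 26 in heart were 1.5-fold lower. A raised floor also shrinks the ratios of dim genes, by construction. The agreement of probe sets of a gene, 0.577 in TA and 0.455 in heart, was 0.745 and 0.606 there. The median of the ER chaperone list in TA ranged from 1.21 to 1.64 over all alternatives, and that of the cell cycle list in TA from -1.06 to -0.64. A list median or a gene's log2 ratio was counted as moved only when it crossed 1.5-fold: 4 of 683 list medians under alternatives and 71 of 2708 log2 ratios of named genes did, and 3 ratios past 1.5-fold changed sign. This hides smaller shifts. Of the 76 list medians, 20 changed sign under at least 1 alternative, most of them from values near 0, and 9 shifted by at least 0.3. Among these, with the floor at the 75th percentile, was the denervation list in TA at 0.57. The red blood cell list in TA was 0.13 with no floor, and the skeletal label list in heart was 0.07 without probe sets that can match several transcripts. Without those probe sets, Psmd13 was 0.53 in TA and 0.69 in heart, and Laptm5 0.36 in heart. The cause was not tested. Other named genes that ended under 1.5-fold with another scaling or choice of probe set include Trdn at -0.19, Myh2 at -0.52 and Ucp3 at -0.52 in TA, and Srebf2 at -0.51, Psat1 at -0.52, Phgdh at -0.56 and Ppargc1a at 0.56 in heart. With the median over probe sets, the atrophy list in TA was 0.07. With random lists not matched on signal, 8 of 72 percentiles of the lists fixed beforehand crossed a bound of the central 95%. In TA these were heat shock at 92.1, embryonic and neonatal sarcomere at 89.1, fatty acid oxidation at 97.49, ribosomal proteins at 69.9, the cardiac label list at 96.4 and the sarcoplasmic reticulum at 2.27. In heart they were glycolysis at 2.83 and the cardiac label list at 87.4. Among the later lists, the mitochondrial unfolded protein response crossed in TA, at 97.2.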

Other observations

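A further group concerned the clock and growth signals. In the later list of clock genes of the phase opposite to the day genes, Nfil3 was 2.16-fold higher in knockout TA and 1.59-fold in heart, and Cry1 1.89-fold and 1.17-fold (medians 0.39 and 0.30, percentiles 98.4 and 98.2, 5 genes). The later list of day-phase clock genes had medians of -0.17 and 0.05, with Dbp 1.75-fold lower in TA and 1.39-fold lower in heart and log2 ratios of 0.57 and 0.66 for Per2. Among growth signals (medians -0.11 and 0.06), the insulin receptor substrate gene Irs2 was 2.24-fold higher in knockout TA and 1.70-fold in heart, Igfbp5 1.58-fold lower in TA and Igfbp3 2.01-fold higher in heart. Interferon response genes had medians of -0.27 in TA (percentile 0.74) and 0.11 in heart, with Bst2 1.72-fold lower in TA. With the floor at the 75th percentile these medians were -0.01 and -0.04, and without probe sets that can match several transcripts that of TA was -0.06. In TA, sterol synthesis genes went both ways around a median of -0.03, with Mvd 2.39-fold higher and Sqle 2.22-fold lower. Proteasome genes had a median of -0.15 in TA (percentile 0.4), or -0.05 without probe sets that can match several transcripts, ribosomal protein genes 0.02, and housekeeping genes -0.04.

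DNA of the embryonic stem cell strain beside the targeted gene may differ from the background and shift its neighbours in both tissues. Among 75 measured genes around Hhatl in gene order on chromosome 9, at most 50 on each side, 0 were at least 1.5-fold different the same way in both tissues. Windows of the same number of genes over all chromosomes, those near Hhatl included, held a median of 1 and at most 6 such genes. This test therefore argued against neighbouring DNA as a source of the shared differences. The test was planned for 100 genes, 50 on each side, but fewer than 50 lie between Hhatl and the end of the chromosome.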
